A study of Mus musculus with 26 samples.

How the data were processed

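Tumour cells (MM3MG-HER2del16, 1000000 per animal) grew in the mammary fat pad of female F1 mice carrying a human CD27 transgene. Vaccinated mice received 20 µl of AdHER2 at 2e11 viral particles per ml in both footpads, and antibody-treated mice received 10 µg of varlilumab. Tumours were taken 14 days after vaccination, live CD45+ cells were sorted, and 10000 cells were loaded per mouse for 5' gene expression and receptor libraries. The labels put all 26 libraries of the 13 mice in batch 1. Per the submitters' processing notes, Cell Ranger (version not given in the sources used here), R 4.4.0 and Seurat 5.3.0 were used, with an mm39 reference to which human CD27 and ERBB2 were added.

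The deposited gene table is named as raw counts, but its values are best described as a score: whole numbers per gene and cell that the authors had corrected for depth by a method not given in the sources used here. The column totals equalled the deposited UMI totals in 288 of 58171 cells. Cells with 501 to 1000 UMIs had a median of 725 deposited UMIs and 1656.5 corrected counts, and the deepest cells, above 10000 UMIs, had 11896 and 2276. The deposited cell table holds counts of UMIs, genes and clone sizes per cell, the percent of mitochondrial UMIs per cell, and columns of other kinds, such as cell names and the cell types given by the authors. The deposited receptor files hold UMI and read counts per contig, and the deposited annotation holds coordinates (unit: other). Cells ranged from 501 to 14999 UMIs, from 202 genes upwards and up to 9.995% mitochondrial UMIs, in 28239 genes, of which 7051 had only an Ensembl identifier.

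Total deposited UMIs were 26198130, 10040893 and 9902361 in control 1 to 3, 46010751, 18853118 and 25089576 in anti-CD27 1 to 3, 23317562, 14674911 and 37477280 in AdHER2 1 to 3, and 26397567, 29866460, 18770715 and 9459846 in combination 1 to 4. Wilson intervals at 95% cover counting error only.

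The 24 deposited cell types were used as given. Conventional CD4 T cells and CD8 T cells joined the authors' resting and activated classes, and macrophages and monocytes formed 1 class. Corrected counts were summed per mouse and class, with 20 or more cells per library and a mean of 20 or more corrected CPM (corrected counts scaled to a common total per library). The log2 values, with a pseudocount of 10, were fitted with limma 3.58.1 (trend and robust, R 4.3.3), with 4 arms in 1 fit and Benjamini-Hochberg adjustment at 0.05. The vaccine effect is the mean of both vaccinated arms minus the mean of both others. The plan had been edgeR on counts, which the deposited unit rules out, so limma was chosen after the values were seen. edgeR 4.0.16 served only on cell numbers. Contrasts of CD4 and CD8 cells with control were not tested, because at most 1 control library held 20 such cells, and combination against anti-CD27 was added for these classes.

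Comparisons, gene lists, most of the alternatives and the choice of genes to name were fixed before the data were examined. The naming rule took the 6 largest rises and 6 largest falls past the threshold with a mean log2 value of 5 or more and no overlap between arms. It left out receptor and immunoglobulin segments and genes with provisional names. It added up to 4 members past the threshold with the smallest p per list, and fixed T cell and macrophage genes. The text names part of the set, and some genes of it are not reported here. The 31 lists were tested with camera at a preset correlation of 0.01, again with an estimated correlation, and with fry.

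Shares per mouse were compared by exact two-sided permutation tests over 28 shares, with vaccine labels permuted within antibody status and antibody labels within vaccine status (Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9). Clones were cells with identical TRA and TRB CDR3 nucleotide sequences. Clone sizes were compared after thinning to 10 paired cells per mouse (1000 draws), or 667 for vaccinated mice. Overlap of TRB CDR3 amino acid sequences was a Jaccard index with 100000 permutations. Expanded and single CD4 cells were compared with the mouse as a block.

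The 3585 barcodes that anti-CD27 1 and anti-CD27 3 share were left out of anti-CD27 3 after first results had been seen, and the cells as deposited were kept as an alternative. Scrublet's method marked 73 of 54586 cells (0.134%), too few to be of use on corrected values, so cells with a doublet receptor pattern (a T cell with more than 1 TRB chain, or another cell with any) were left out as an alternative instead. Further alternatives changed the pseudocount, the filter, the cells per library, the libraries in the fit, the normalization (quantile), library weights, the depth (a covariate, or cells of 1500 to 4000 UMIs), the cells (only those typed as CD4 T cells), the replicate block, the clone definition, and anti-CD27 2 and 3 as 1 sample, and left out each mouse in turn. Recovery was tested on simulated changes in 100 genes at each fold.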

Results

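Live CD45+ cells were sorted from mammary tumours of 13 mice and sequenced as 5' single-cell libraries, with a gene expression library and a T cell receptor library per mouse (26 libraries). The mice carried a human CD27 transgene and MM3MG-HER2del16 tumours, a mouse mammary line expressing an oncogenic splice form of human HER2. Control mice received control IgG (n = 3), and the other arms received varlilumab, an agonist antibody to human CD27 (anti-CD27, n = 3), an adenoviral vaccine encoding HER2 (AdHER2, n = 3), or both (combination, n = 4). The deposited matrix held 58171 cells, between 1189 and 9604 per library, with total UMIs between 9459846 and 46010751 and median UMIs per cell between 2091.5 and 9042.5. Libraries anti-CD27 1 and anti-CD27 3 shared 3585 cell barcodes where chance would give 64.8, and 86.6% of these had the same deposited type in both. The repeated cells were left out of anti-CD27 3, which left it 3643 cells and left 54586 in all. The 13 mice and not the cells are the replicates in every test.

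The first question was what the vaccine did to the leukocytes inside the tumour. T cells took 4.80% ± 0.984 (SD, n = 3) of sorted cells in control tumours and 12.4% ± 4.82 (n = 3) with anti-CD27. They took 64.1% ± 6.01 (n = 3) with AdHER2 and 70.0% ± 11.2 (n = 4) with the combination. Within T cells, counted by the authors' classes, CD8 cells, the killer lineage, rose by 28.8 points with vaccination. Conventional CD4 helper cells rose by 10.3 points on the same count. These classes leave 3832 T cells in a class called DN, in which 0 cells were above 0 for Cd4, Cd8a or Cd8b1. Cytotoxic CD8 T cells rose by 18.1 points of sorted cells, NK cells by 9.90, regulatory T cells by 14.8 and B cells by 8.15. Of the authors' types of tumour-associated macrophages (TAM), the 1 named only TAM fell by 32.0 points, MDSC-like TAM by 19.8 and Fcrl2+ TAM by 5.43. Osteoclast-like, Cxcl13+ and Lrmda+ TAM fell by 3.03, 1.38 and 1.16, so the fall of these macrophages together was larger than 32.0 points. Regulatory T cells, which restrain other T cells, differed by −18.1 points as a share of CD4 T cells in vaccinated against unvaccinated mice. This share sets the authors' regulatory class against that class plus conventional CD4 T cells, while the rise of 14.8 points counts their regulatory type. By type, regulatory and CD4 T cells took 1.32 and 0.908% of sorted cells in controls and 3.37 and 2.19% with anti-CD27. They took 18.9 and 12.5% with AdHER2 and 15.5 and 14.1% with the combination. The fall from control to AdHER2 thus depends on the definition, and so does the rise of CD4 cells within T cells. By type, CD4 T cells moved about in step with all T cells. They took 0.908 of 4.80% in controls, 2.19 of 12.4% with anti-CD27, 12.5 of 64.1% with AdHER2 and 14.1 of 70.0% with the combination. The share by class was 73.3% ± 9.65 in controls (n = 3), 64.6% ± 17.1 with anti-CD27 (n = 3), 58.8% ± 5.58 with AdHER2 (n = 3) and 42.9% ± 5.06 with the combination (n = 4). Few cells stand behind the control values: control 1 to 3 held 25, 21 and 5 regulatory, 14, 8 and 1 conventional CD4 and 29, 14 and 0 CD8 cells. In an exact two-sided permutation test with labels permuted within antibody status (700 arrangements), T cells, CD8 cells and conventional CD4 cells each reached p = 0.00143, the smallest possible, with an adjusted p of 0.00235 over 28 shares. The regulatory share had an exact p of 0.00857 and an adjusted p of 0.0114. Dendritic cells (exact p = 0.920) and γδ T cells (exact p = 0.241) did not pass. Shares sum to 100% in each mouse, so a rise in 1 type lowers the others, and absolute cell numbers per tumour are not given in the sources used here.

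A further question was what CD27 agonism added, alone or on top of the vaccine. A subset that the authors call VR T cells, an abbreviation the labels do not spell out, rose with the antibody by 2.09 points. It took 0.122% ± 0.0468 of sorted cells in controls (n = 3), 0.339% ± 0.0335 with anti-CD27 (n = 3), 2.74% ± 0.564 with AdHER2 (n = 3) and 6.70% ± 1.06 with the combination (n = 4). MDSC, immature myeloid cells, rose by 1.83 points, from 1.96% ± 1.05 to 4.52% ± 1.44 without the vaccine and from 0.471% ± 0.212 to 1.56% ± 0.453 with it. The exact permutation p was 0.00143 for VR T cells, the smallest possible, and 0.00286 for MDSC, each with an adjusted p of 0.04. Across the alternatives the adjusted p ran from 0.0160 to 0.219 for VR T cells and from 0.02 to 0.219 for MDSC. With anti-CD27 2 and 3, which share many receptor clones, counted as 1 mouse, both reached 0.08, as did MDSC among cells with 1000 or more UMIs. Leaving out control 1, 2 or 3 gave VR T cells an adjusted p of 0.08 each time and MDSC 0.2, 0.133 and 0.12. Without anti-CD27 3 both gave 0.08, without AdHER2 3 both gave 0.0933, and without any 1 of combination 1, 2, 3 or 4 both gave 0.07, each from fewer possible arrangements. Regulatory T cells as a share of CD4 T cells differed by −12.3 points with the antibody and did not pass (exact p = 0.0543, adjusted p = 0.251). Conventional CD4 cells, counted by class, changed by 6.16 points of T cells (exact p = 0.0200, adjusted p = 0.14) and B cells by −3.95 points (exact p = 0.0143, adjusted p = 0.133), and neither passed.

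The combination was then set against AdHER2 alone, where 4 mice against 3 cannot give an exact p under 0.0286. Counted by class, regulatory T cells took 58.8% ± 5.58 of CD4 T cells with AdHER2 (n = 3) and 42.9% ± 5.06 with the combination (n = 4). The difference was −15.9 points, and no mouse overlapped the other arm. By type, regulatory and CD4 T cells took 18.9 and 12.5% of sorted cells with AdHER2 and 15.5 and 14.1% with the combination. That has the same direction but a smaller gap, so the size depends on the definition. As shares of sorted cells, B cells differed by −7.86 points, γδ T cells by −2.75 and VR T cells by 3.95, also with no overlap. Each of these 3 and the regulatory share by class reached the smallest exact permutation p of 0.0286 and an adjusted p of 0.2, so none passed. Conventional CD4 T cells, counted by class, differed by 7.13 points of T cells (exact p = 0.0857, adjusted p = 0.4). Anti-CD27 or AdHER2 against control, with 3 mice each, cannot reach an exact p under 0.1. A test of whether the antibody acted differently with and without the vaccine, chosen after the results were seen, called γδ T cells. These innate-like T cells were 2.93 points higher with anti-CD27 than in controls and differed by −2.75 points between combination and AdHER2. That is an interaction of −5.67 points (exact permutation p = 0.00143, the smallest possible, adjusted p = 0.04). VR T cells, with the same exact and adjusted p, reached 0.08 with anti-CD27 2 and 3 counted as 1 mouse. No such check, nor one with a mouse left out, is given for the interaction.

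**Figure D1:**
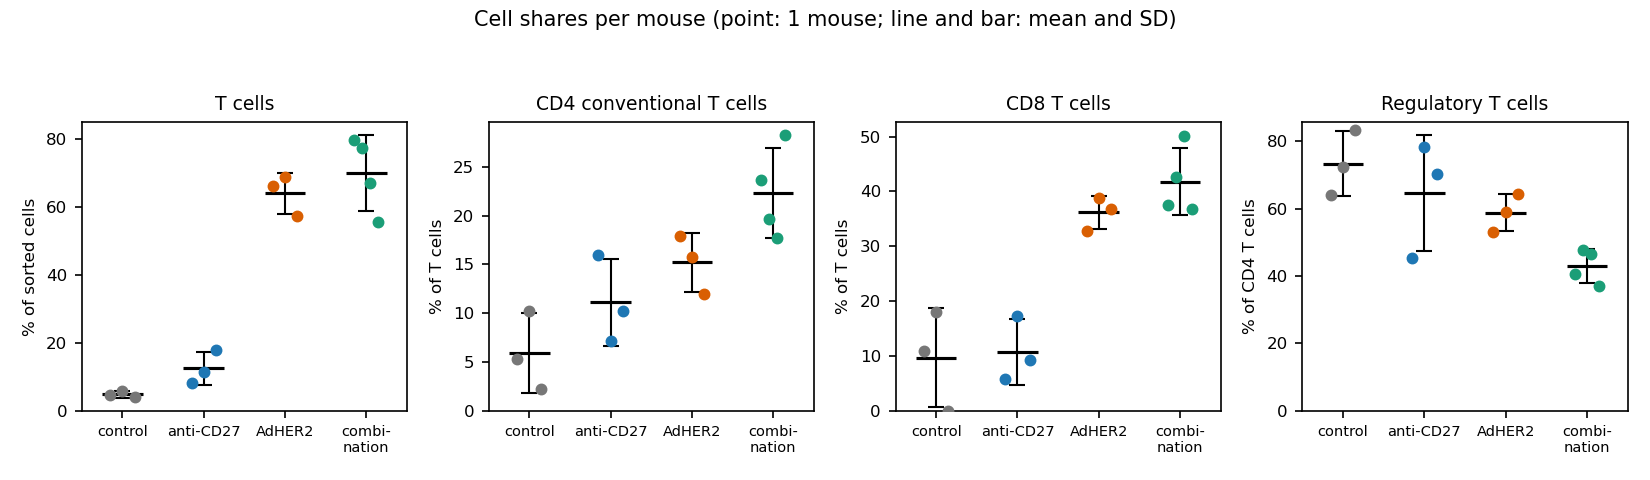
Shares in percent (vertical axes) of T cells among sorted cells, conventional CD4 and CD8 cells among T cells, and regulatory T cells among CD4 T cells, by arm. Points are mice and bars show mean and SD. All shares are counted by the authors' classes. The regulatory share averages 73.3% in controls, 64.6% with anti-CD27, 58.8% with AdHER2 and 42.9% with the combination. Control 1 to 3 held 25, 21 and 5 regulatory and 14, 8 and 1 conventional CD4 cells.

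In conventional CD4 T cells the question was which programme CD27 agonism adds to vaccination. Genes of Th1 cells, the helper type that makes interferon gamma, had a median log2 change of 0.39 between combination (n = 4) and AdHER2 (n = 3) over 16 genes. Cytotoxic effector genes, which encode granzymes and killer receptors, had a median of 0.68 over 12 genes. Camera gave adjusted p = 8.0e-13 and 8.6e-21, and both calls held, with adjusted p = 0.0113 with an estimated correlation for each. With fry, a set test against no change, the adjusted p was 0.141 and 0.122. The Th1 median was 0.25 without combination 4 and 0.22 with depth as a covariate, the cytotoxic median 0.68 and 0.80, and camera still called each. By the authors' types, 64.8 to 71.4% of the class were CD4 T cells with AdHER2 and 46.5 to 67.2% with the combination. VR T cells were 8.22 to 13.7% and 18.7 to 23.2%, exhausted CD8 T cells 7.04 to 9.29% and 7.48 to 12.6%, and cytotoxic CD8 T cells 1.35 to 4.11% and 1.93 to 4.25%. Among cells typed as CD4 T cells alone the Th1 median was 0.38 and the cytotoxic median 0.42 over the same genes (0.59 over those that passed the filter in these cells), and camera called both. No single gene passed limma among 7137 tested, with 208 at an unadjusted p under 0.05, against 400 genes passing with library weights, which were chosen after the result was seen. Adjusted over the list alone, 4 cytotoxic genes and 0 Th1 genes passed, against 0 of either over all genes. Bcl2, a survival factor (ENSMUSG00000057329, chromosome 1, 106465908 to 106642004, mm39), stood at 244 ± 72.1 corrected CPM (depth-corrected counts scaled to a common total) with AdHER2 and 455 ± 199.8 with the combination (log2 difference 0.82, SE 0.27). Ifng, the Th1 cytokine, stood at 212 ± 51.6 and 232 ± 23.2, and Il7r, the interleukin 7 receptor, at 557 ± 39.4 and 569.7 ± 184. Human CD27 itself, the antibody's target, differed by −0.01. Type I interferon genes had a median of −0.54 (camera adjusted p = 1.1e-05), a call lost at adjusted p = 0.1695 with an estimated correlation. Mitochondrial transcripts had a median of 0.23 and macrophage markers 0.43, calls lost at adjusted p = 0.274 and 0.1695 with an estimated correlation. Genes changed 2-fold in simulated data were recovered in 12% of cases and 4-fold in 92%, with 5 false calls, so changes near 2-fold were mostly out of reach in this class.

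**Figure D2:**
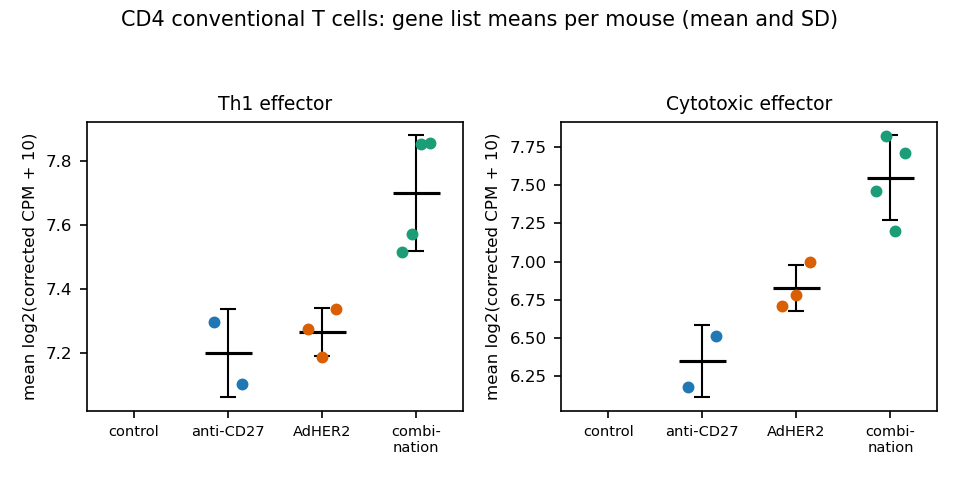
Mean log2 corrected CPM plus 10 (vertical axes) over the Th1 and the cytotoxic genes in conventional CD4 T cells, by arm. Points are mice and bars show mean and SD; cytotoxic genes average 6.83 with AdHER2 and 7.55 with the combination, and control mice had too few cells to be measured.

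Control tumours held at most 14 conventional CD4 T cells. The vaccine's effect on these cells was thus read as combination (n = 4) against anti-CD27 alone (n = 2 mice with 20 or more cells). This comparison was added after the cell numbers were seen. The 2 mice are anti-CD27 1 and 3, whose expression libraries shared 3585 barcodes, left out of anti-CD27 3. Of its 645 other T cells, 29 still matched the receptor library of anti-CD27 1. Il4, the Th2 cytokine (ENSMUSG00000000869, chromosome 11, 53493809 to 53509496, mm39), fell by 2.70 on the log2 scale (SE 0.36, limma adjusted p = 0.00606), from 348 ± 163 to 44.7 ± 17.9 corrected CPM. Gata3, the transcription factor of Th2 cells, fell by 1.15, and Ccr4 and Ccr8, chemokine receptors of Th2 and tumour regulatory T cells, fell by 1.87 and 1.81. Gzmk, a granzyme of effector cells (ENSMUSG00000042385, chromosome 13, 113308142 to 113362442, mm39), rose by 2.56 (SE 0.40, adjusted p = 0.0133). Ly6c2, a surface marker of effector T cells, rose by 2.85, and mouse Cd27 by 1.27. Of 7 Th2 genes 3 fell over all genes and 6 adjusted over the list alone. Of 14 regulatory T cell genes 3 fell, against 10 lower and 1 higher adjusted over the list alone. Of 12 cytotoxic genes 1 rose, against 8 adjusted over the list alone. Camera called all 3 lists, and each was lost at adjusted p = 0.136 with an estimated correlation. In all, 57 genes changed (27 higher, 30 lower). The class differed in its make-up: VR T cells were 14 of 84 and 3 of 66 cells in anti-CD27 1 and 3, against 18.7 to 23.2% in the combination mice, and exhausted CD8 T cells 10 of 84 and 17 of 66, against 7.48 to 12.6%. Among cells typed as CD4 T cells alone 126 genes changed (79 higher, 47 lower), Il4, Gata3, Gzmk, Ly6c2 and Cd27 among them, while Ccr4 and Ccr8 no longer passed. Quantile normalization called 46 genes (17 higher, 29 lower), a fit of only these arms 10 and a fit without the filter 87. The count was 310 without anti-CD27 1 and 31 without anti-CD27 3, where the lone anti-CD27 mouse is assumed to vary like the other groups, 29 without combination 1 and 26 without combination 3.

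In CD8 T cells no gene passed limma between combination (n = 4) and AdHER2 (n = 3) among 6999 tested, with 39 at an unadjusted p under 0.05, against 1218 passing with library weights. Values here are relative to the median of all genes, which was −0.127 and moved to −0.003 under quantile normalization. Gzmb, a granzyme that kills target cells, differed by 0.71 relative to it, Bcl2 by 0.46, Ifng by −0.12 (−0.25 as fitted and −0.29 under quantile normalization) and Pdcd1, the PD-1 checkpoint receptor, by −0.47, none past the threshold. Mitochondrial transcripts, a sign of RNA quality, had a median of 0.40 relative to it and macrophage markers 0.42, both camera calls lost at adjusted p = 0.274 with an estimated correlation. Against anti-CD27 alone (n = 3), CD8 cells of the combination arm changed in 131 genes (83 higher, 48 lower). Ly6a, an activation marker, rose by 2.39 (SE 0.27, limma adjusted p = 0.00171), and Ccl5 and Ccl4, chemokines of effector cells, rose by 1.36 and 1.25. Cxcr3, which guides T cells to interferon-induced chemokines, rose by 1.32, and Gbp2, an interferon-induced GTPase, by 1.41. Tnfrsf9 and Tnfrsf4, costimulatory receptors of recently activated T cells, fell by 2.13 and 2.35, Ikzf2, a factor of regulatory and exhausted cells, fell by 2.05, and Prf1, the pore-forming protein perforin, fell by 0.97. Spp1 and Fn1, abundant in tumour macrophages, fell by 2.65 and 2.11 in the same cells. The count was 1087 without anti-CD27 1, 18 without combination 1, 28 without combination 2, 43 without combination 3 and 18 without combination 4, and it was 15 with 10 cells per library, 8 in a fit of only these arms, 55 with pseudocount 1, 54 without the filter, 209 with library weights and 214 (116 higher, 98 lower) under quantile normalization. The class differed in its make-up: cells that the authors typed as exhausted were 3 of 30, 34 of 44 and 42 of 59 in anti-CD27 1, 2 and 3, against 6.59 to 16.6% in the combination mice. The changes are thus those of the whole class and were not shown within 1 type. Regulatory T cell genes fell in 3 of 11 cases (7 adjusted over the list alone), with adjusted p = 0.382 with an estimated correlation.

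Regulatory T cells could be followed from control tumours (n = 2 mice, with 25 and 21 cells) into vaccinated ones (n = 3 and 4), beside anti-CD27 alone (n = 3). With vaccination 923 genes changed by limma (753 higher, 170 lower), against 502 under quantile normalization (257 higher, 245 lower), 415 with depth as a covariate and 75 with library weights. That scaling moved the median of all genes from 0.23 to 0.019, so the changes that follow are relative to the median, while limma tests the fitted change. Klrg1, a marker of terminally differentiated regulatory T cells, rose by 1.16 (1.39 as fitted, limma adjusted p = 0.00915), and Il10, a suppressive cytokine, by 0.89. Ifng rose by 1.17 and Bcl2 by 0.94. Tigit and Entpd1, an inhibitory receptor and the ATP-degrading enzyme CD39, rose by 0.67 and 0.39. S1pr1, which guides cells out of lymph nodes, rose by 0.68. Foxp3, the factor that defines these cells, differed by −0.12 relative to the median, but by 0.11 as fitted (adjusted p = 0.593) and 0.16 under quantile normalization. Naive and memory genes rose in 8 of 15 cases (10 adjusted over the list alone), with adjusted p = 0.433 with an estimated correlation. The stress genes Hspa1a, Hspa1b and Jun rose by 2.69, 1.98 and 0.77 in the same cells, and Junb fell by 0.90 (0.33 under quantile normalization). Macrophage transcripts moved as well, as Apoe fell by 3.38, C1qc fell by 2.94 and the antigen presentation gene Cd74 fell by 2.23 relative to the median. Without control 1 or control 2, where the lone control mouse is assumed to vary like the other groups, the count was 1755 and 2671, and without AdHER2 1, AdHER2 2 and combination 1 it was 472, 470 and 615. Between combination and AdHER2 no regulatory T cell gene passed limma among 7079, with 11 at an unadjusted p under 0.05, and between combination and anti-CD27 the count was 0, with 243. Library weights gave 201 and 65 genes.

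Macrophages and monocytes held cells in every arm, and vaccination changed 1269 of 6049 genes (560 higher, 709 lower; 7 vaccinated against 6 unvaccinated mice). Rsad2, an antiviral enzyme of the type I interferon response (ENSMUSG00000020641, chromosome 12, 26492745 to 26506451, mm39), rose by 2.05 on the log2 scale (SE 0.32, limma adjusted p = 0.00282). Ifit2, Oasl1 and Oas2, antiviral effectors of the same response, rose by 1.46, 1.34 and 1.21, and 17 of 18 type I interferon genes rose, over all genes and adjusted over the list alone. Acod1, which makes the antimicrobial metabolite itaconate, rose by 1.66, Tnf by 1.11 and Irf1, a factor of interferon responses, by 1.24. Spp1, the osteopontin gene of tissue-remodelling macrophages (ENSMUSG00000029304, chromosome 5, 104582984 to 104588916, mm39), fell by 1.80 (SE 0.31, adjusted p = 0.00414), and the mannose receptor Mrc1 and complement gene C1qa fell by 1.67 and 1.06. Of 13 tissue-remodelling genes 9 fell, against 9 lower and 1 higher adjusted over the list alone. Camera called both lists, and the type I interferon list was lost at adjusted p = 0.153 with an estimated correlation, the tissue-remodelling list at adjusted p = 0.283 with an estimated correlation. T cell transcripts moved as well: Cd3e rose by 2.20 and Nkg7 by 2.39 in these cells. The count was 2277 without AdHER2 3, 779 without control 1, 795 without control 2, 667 without anti-CD27 1, 796 without anti-CD27 2 and 600 without anti-CD27 3, 597 without the filter, 700 with anti-CD27 2 and 3 as 1 sample and 2354 with library weights.

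Anti-CD27 alone was compared with control in macrophages (n = 3 each), cells in which human CD27 was low. Clec4e, a receptor for damaged cells and mycobacterial lipids (ENSMUSG00000030142, chromosome 6, 123258748 to 123266829, mm39), rose from 49.97 ± 1.36 to 275 ± 17.0 corrected CPM (log2 change 2.25, SE 0.26, limma adjusted p = 0.000835). Ccl4 and Ccl3, chemokines that draw T cells and monocytes, rose by 1.90 and 1.68. Zfp36, which destabilises cytokine messenger RNA (ENSMUSG00000044786, chromosome 7, 28076209 to 28079678, mm39), rose by 1.70 (SE 0.18, adjusted p = 0.000597), and the heat shock gene Hspa1b rose by 3.09. Inflammatory myeloid genes had a median change of 1.32, with 2 of 11 higher over all genes and 8 adjusted over the list alone, and the camera call held with adjusted p = 0.00103 with an estimated correlation. Stress genes also moved, with 3 of 18 higher over all genes and 10 higher and 1 lower adjusted over the list alone, with adjusted p = 0.149 with an estimated correlation. In all, 10 genes changed (7 higher, 3 lower). The count was 3 without control 1, control 2, anti-CD27 1, anti-CD27 2 or anti-CD27 3, 0 of the genes passed in cells matched at 1500 to 4000 UMIs, and the count was 50 without the filter, 29 with 50 cells per library, 18 under quantile normalization, 294 in a fit of only these arms, 3 with anti-CD27 2 and 3 as 1 sample and 2098 with library weights. Ccl4 (ENSMUSG00000018930, chromosome 11, 83553410 to 83555509, mm39) and Zfp36 were also the only genes whose response to the antibody differed between vaccinated and unvaccinated mice by limma, by −2.49 and −1.70 (adjusted p = 0.00472 and 0.0158). That count of 2 was 55 without AdHER2 3, 5 without control 3, 1 without AdHER2 1, AdHER2 2, control 1, control 2, combination 1, combination 4, anti-CD27 1 or anti-CD27 2, 3 (1 higher, 2 lower) under quantile normalization, 0 without the filter, 1 with 50 cells per library, 4 with pseudocount 50 and 138 with library weights.

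Between combination (n = 4) and AdHER2 (n = 3), interferon-gamma response genes of macrophages had a median log2 change of 0.98. Over all 6049 genes none passed limma, with 452 at an unadjusted p under 0.05. Adjusted over the list alone 13 of 17 interferon-gamma genes were higher, and the camera call (adjusted p = 3.5e-15) was lost at adjusted p = 0.221 with an estimated correlation. Cd274, the PD-L1 ligand that restrains T cells (ENSMUSG00000016496, chromosome 19, 29344855 to 29365495, mm39), stood at 97.0 ± 15.8 corrected CPM with AdHER2 and 295 ± 71.8 with the combination (log2 difference 1.49, SE 0.27, limma adjusted p = 0.0862). Cxcl9, a chemokine that attracts T cells through Cxcr3, stood at 323 ± 137 and 969.7 ± 299.5 (log2 difference 1.58, SE 0.48, adjusted p = 0.575). Arg1, which depletes arginine, differed by 1.79 (adjusted p = 0.719) and Spp1 by −0.55 (adjusted p = 0.769). Hypoxia and glycolysis genes had a median of 0.74, with 6 of 15 higher adjusted over the list alone and 0 over all genes, and the camera call was lost at adjusted p = 0.0942 with an estimated correlation. Without AdHER2 3, which held 1693 of these cells where AdHER2 1 and AdHER2 2 held 97 and 37, the count of changed genes was 142. The make-up of the class varied between mice. TAM and MDSC-like TAM numbered 40 and 48, 15 and 19, and 983 and 434 in AdHER2 1 to 3. In combination 1 to 4 they numbered 57 and 149, 57 and 108, 55 and 42, and 167 and 109. The changes are those of the whole class and were not shown within 1 type.

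**Figure D3:**
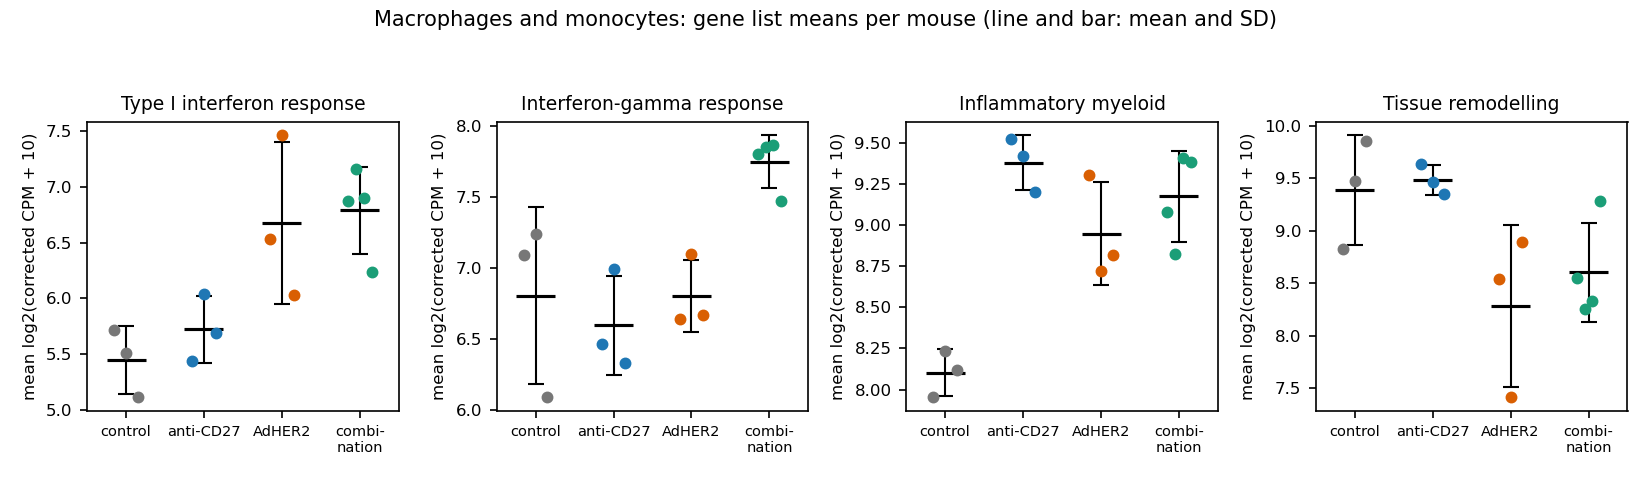
Mean log2 corrected CPM plus 10 (vertical axes) over 4 gene lists in macrophages and monocytes, by arm. Points are mice and bars show mean and SD; interferon-gamma genes average 6.81 with AdHER2 and 7.75 with the combination, and inflammatory genes 8.10 in controls and 9.38 with anti-CD27.

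The receptor libraries allowed CD4 T cells of expanded clones, with 2 or more cells, to be compared with single ones inside each of the 7 vaccinated mice. Cxcr6, a receptor that retains T cells in tissue (ENSMUSG00000048521, chromosome 9, 123635540 to 123640825, mm39), was higher in expanded cells of 7 of 7 mice (log2 change 0.49, SE 0.07, limma adjusted p = 0.00207). Tnf, an effector cytokine, and Lgals3, the galectin-3 gene, were higher by 0.57 and 0.75 in 7 of 7 mice, and Nkg7, a cytotoxic granule gene, by 0.53 in 6 of 7. Id2, a factor of effector differentiation, was higher by 0.33. Tcf7, the factor of stem-like T cells, fell by 0.56, Il7r by 0.52 and Klf2, which keeps T cells in circulation, by 0.31, each in 7 of 7 mice. Of 15 naive and memory genes 6 fell, against 11 adjusted over the list alone. Of 16 Th1 genes 3 rose, against 7 adjusted over the list alone. Both camera calls were lost, with adjusted p = 0.0528 with an estimated correlation for naive and memory genes and adjusted p = 0.0503 with an estimated correlation for Th1 genes. Ifng differed by 0.47 (adjusted p = 0.0766). In all, 82 of 7090 genes changed (36 higher, 46 lower). Without AdHER2 2, AdHER2 3, combination 2 and combination 3 the count was 44, 13, 40 and 14, and with 3 or more cells per clone it was 16. The class holds cells typed as exhausted CD8 (7.04 to 12.6% per mouse) and cytotoxic CD8 T cells (1.35 to 4.25%), types in which expanded clones held a higher mean share than in CD4 T cells, a difference not tested and absent for cytotoxic CD8 T cells of combination 4 (62 of 195 against 44 of 138 cells). Among cells typed as CD4 T cells alone 28 genes changed (13 higher, 15 lower). Cxcr6, Tnf, Lgals3, Tcf7 and Il7r still passed, while Nkg7, Id2 and Klf2 did not.

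Clone sizes were compared at equal numbers of paired cells to ask whether treatment expanded clones. The share of T cells with a TRB contig was not matched and ran from 30.8% in controls to 81.1% with the combination. With 10 paired T cells drawn per mouse, 1.47% ± 2.55 of cells were in expanded clones in controls (n = 3), 6.60% ± 4.66 with anti-CD27 (n = 3), 3.38% ± 2.48 with AdHER2 (n = 3) and 2.30% ± 1.68 with the combination (n = 4). The vaccine effect was −1.20 points (exact permutation p = 0.501), a depth at which few clones can repeat. At 667 cells per vaccinated mouse, expanded clones held 38.4% ± 3.53 with AdHER2 and 36.9% ± 11.1 with the combination (exact permutation p = 0.914), and distinct clones numbered 486 ± 25.5 and 498 ± 66.9 (exact permutation p = 0.857). In the vaccinated mice expanded clones held 70.3% ± 15.6 of paired exhausted CD8 T cells (n = 7), 63.4% ± 15.1 of cytotoxic CD8 T cells (n = 7), 41.4% ± 8.18 of regulatory T cells (n = 7) and 36.1% ± 7.31 of CD4 T cells (n = 7). The largest clone held from 33 of 3230 paired cells in combination 1 to 106 of 1240 in AdHER2 2, or 8.55% (95% Wilson interval 7.12 to 10.2), among the 7 vaccinated mice, and from 5 of 224 to 16 of 135 with anti-CD27 alone. Pairs of vaccinated mice shared 1.46% of TRB CDR3 sequences (Jaccard index) and other pairs 0.711%, a difference of 0.746 points (permutation p = 0.137, 100000 resamples). With sequences carried by the same barcode in more than 1 library left out, the difference was 0.916 points (permutation p = 0.00749). For the sharing of TRB CDR3 between mice without anti-CD27 2 or anti-CD27 3, whose receptor libraries share 93 paired clones, the difference was 1.09 and 1.10 points (permutation p = 0.00135 each). With nucleotide sequences it was −0.0367 points (permutation p = 1), and 0.295 and 0.277 without either of these libraries (permutation p = 0.00135 each). Thinned to the smallest library it was −0.0434 (permutation p = 0.939), and 0.219 and 0.191 without either (permutation p = 0.191 and 0.270). With the Morisita-Horn index it was 0.410 (permutation p = 0.920), and 2.32 and 1.96 without either (permutation p = 0.253 and 0.362). Of 15426 CDR3 sequences, 1 was present in all 7 vaccinated mice.

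The antibody's target was the human CD27 transgene (ENSG00000139193, a separate reference sequence added to mm39, 301 to 7064). In vaccinated mice exhausted CD8 T cells carried 2.27 ± 0.717 corrected counts of human CD27 per cell (n = 7), regulatory T cells 1.08 ± 0.161, cytotoxic CD8 T cells 0.859 ± 0.108 and CD4 T cells 0.593 ± 0.0959. It was above 0 in 40.1% ± 4.96 of CD4 T cells at a median of 3743 UMIs per cell, against 0.589% ± 0.992 of MDSC-like macrophages, which should lack it, at 7756. In TAM it was above 0 in 3.63% ± 4.36 of cells at a median of 6830 UMIs. γδ T cells (2.65%) and NK cells (1.41% ± 1.36, at a median of 4731 UMIs) lay near that background. Mouse Cd27 (ENSMUSG00000030336, chromosome 6, 125209585 to 125213973, mm39) was above 0 in 22.04% ± 2.45 of NK cells in the same mice and in 43.0% of regulatory T cells. NK cells were thus positive for the mouse gene and near background for the transgene. In γδ T cells mouse Cd27 was above 0 in 2.485% ± 1.72 of cells, so these were low for both genes.

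**Figure D4:**
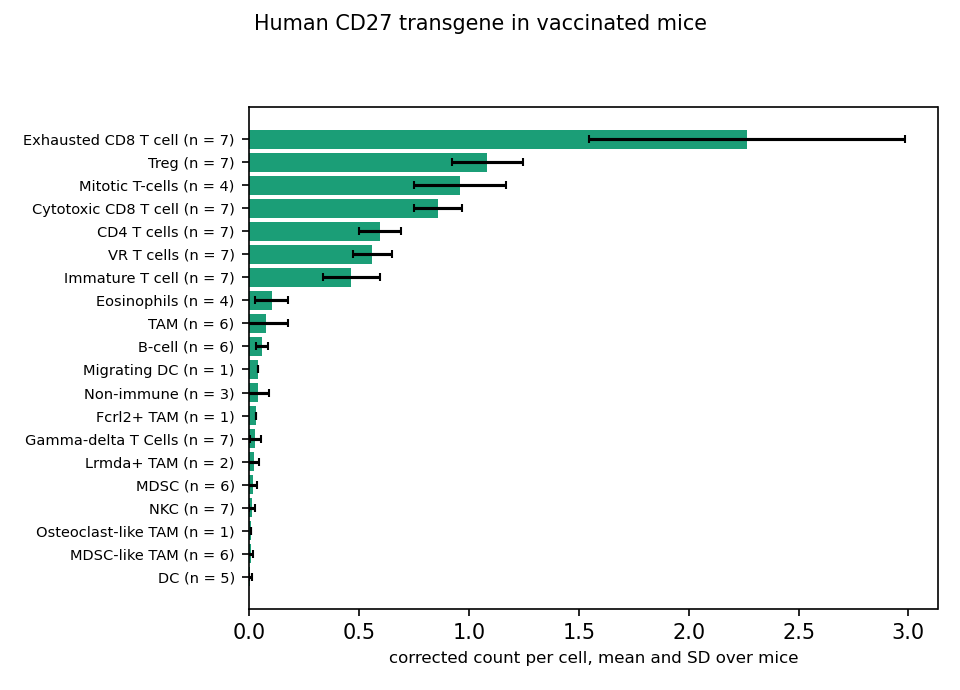
Corrected count of the human CD27 transgene per cell (horizontal axis) by deposited cell type in vaccinated mice. Bars are means and lines the SD over mice with enough cells; exhausted CD8 T cells average 2.27, regulatory T cells 1.08 and NK cells 0.0141.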

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

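The tests of depth for type I interferon genes in macrophages, of free RNA of cytotoxic cells and the mix of cell types in CD4 T cells, of the interaction in cell shares, and all counts of other splits were chosen after the result was seen.

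Among 4 combination mice, 168 values were checked for a mouse far from the others, and 16 lay beyond the critical ratio of gap to range. Chance flags about 1 in 20 groups, or 8.4 here. Combination 4 stood apart in immature T cells (ratio 0.899, with 8.77% against 1.31 to 2.06% in the other mice), non-immune cells (0.831), TAM (0.867, with 10.3% against 0.838 to 2.10%), Lrmda+ TAM (0.883) and osteoclast-like TAM (0.944). It also stood apart in Mctp2 of CD4 T cells (0.865), S1pr1 of regulatory T cells (0.857), and C1qa (0.972), Cbr2 (0.883) and Dusp1 (0.911) of macrophages. The same mouse had the highest mean of tissue-remodelling macrophage genes in CD8 T cells (0.975) and the lowest mean of interferon-gamma genes in macrophages (0.843, at 7.47 against 7.81 to 7.87). Combination 3 stood apart in Ifng (0.886) and Igfbp7 (0.839) of CD8 T cells, and Oasl1 (0.885) and Nfkbia (0.865) of macrophages. The cause was not tested.

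Several responses to the antibody differed between vaccinated and unvaccinated mice. γδ T cells differed by −5.67 points, Ccl4 and Zfp36 of macrophages by −2.49 and −1.70. Camera also called list medians in macrophages for inflammatory genes (−0.97), stress genes (−0.96), naive and memory genes (−0.74), interferon-gamma genes (1.23), MHC class I genes (0.35), fibroblast markers (2.98) and erythrocyte and platelet markers (2.03). None of these lists held with an estimated correlation, the closest being the inflammatory genes (adjusted p = 0.0510). Of 100 splits, 6 called as many genes as the 2 of the interaction, so chance cannot be excluded. The highest other split called 1942, which may reflect a structure of the samples and was not tested.

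In data outside the planned comparisons, 3585 barcodes were present in both anti-CD27 1 and anti-CD27 3, and 93 paired clones in the receptor libraries of both anti-CD27 2 and anti-CD27 3. Cells other than T cells carried a TRB contig in 1.84% of cases with AdHER2 and 1.37% with the combination, against 0.226% ± 0.192 in controls.

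The first pattern is the rise of type I interferon genes in macrophages of vaccinated mice. T cell RNA took 2.01 to 9.39% of macrophage sums in vaccinated mice and 0.231 to 1.03% in others, yet it covered 1.6% of the rise of the median gene, which argues against it as the whole cause. Depth as a covariate left 15 of 17 genes called (88.2%), which argues against depth. Within single subtypes the median change was 0.49 in TAM and 0.77 in MDSC-like TAM against 1.12 in the class, at least 44.1%. The subtype values leave out AdHER2 2, which had 15 and 19 such cells, while the class value includes it. A shift between subtypes may account for part of the rise, but the values do not come from the same mice. The vaccine itself stays among the open explanations. For the 1269 changed genes of the class as a whole, 2 of 100 splits, the real one included, called as many. That is under the 0.05 threshold, but the other split called 1490, so chance is unlikely rather than excluded for that count. Splits were not run for the list alone.

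The second pattern is the rise of stress and inflammatory genes in macrophages with anti-CD27 alone. In cells of matched depth the median change was 0.99 against 1.10, or 89.6%, which argues against depth, although no single gene passed there. Stress genes changed by 0.34 in B cells and 0.75 in NK cells against 0.73 in macrophages, at least 46.7%, so handling of the tissue cannot be told apart from the antibody for the stress genes. Within TAM the change was 0.64 and within MDSC-like TAM 1.20, at least 58.0% of the class, so a shift between subtypes also stays open. With 10 splits the count cannot reach a share under 0.05: 1 split, the real one, called 10 genes, and the highest other called 1.

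The third pattern is the higher Th1 and cytotoxic gene level in CD4 T cells of the combination arm. Without VR T cells the median change was at least 102% of that in the class, which argues against these cells as the whole cause. Among cells typed as CD4 T cells alone the same Th1 genes changed by 0.38, or 99.1% of the class, and the same cytotoxic genes by 0.42, or 61.7% (0.59 in a fit whose own filter kept fewer of them). The mix of cell types is thus argued against for the Th1 genes and may account for part of the cytotoxic change. In cells of matched depth the differences of arm means were 113% (cytotoxic) and 123% (Th1) of those in all cells, and a fit in those cells gave 0.76 and 0.48 against 0.68 and 0.39. With depth as a covariate the cytotoxic median was 0.80 and the Th1 median 0.22, so depth is argued against for the cytotoxic genes and may account for part of the Th1 change. Free RNA of cytotoxic cells would also enter regulatory T cells, which showed 11.7% of the rise of the median cytotoxic gene, so this too is argued against. An effect of CD27 agonism on helper cells may be the source, as a hypothesis found and tested on the same data. The real split called 0 genes, a count that 35 of 35 splits reach by definition, so it says nothing about chance. The highest other split called 766, which may reflect a structure of the samples and was not tested. In these cells, with values centred on each arm, AdHER2 1 correlated with combination 1 and 2 (0.48 and 0.46). It correlated inversely with combination 3 and 4 (−0.31 and −0.46), which follows in part from the centring.

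For the other comparisons, chance is unlikely rather than excluded for expanded CD4 T cells (1 of 64 splits, the real one, which is the fewest possible, 82 genes, highest other 1). For CD8 T cells of combination against anti-CD27 (1 of 35, 131 genes, highest other 17) chance is unlikely only if anti-CD27 2 and 3 are separate animals, which is not settled. For regulatory T cells with vaccination 2 of 100 splits, the real one included, called as many as its 923 genes. That is under the 0.05 threshold, but the other split called 945, so chance is unlikely rather than excluded. That comparison holds 2 control mice, with 25 and 21 cells. Where the real count was 0, 35 of 35 splits reach it by definition, and the count says nothing about chance. For combination against AdHER2 this holds in CD8 T cells (highest other 49), regulatory T cells (22) and macrophages (504, which may reflect a structure of the samples). It also holds in regulatory T cells for combination against anti-CD27 (0).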

How the results depend on the processing

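Tests with quantile normalization, library weights, other pseudocounts, depth, the doublet receptor pattern, cells typed as CD4 T cells and anti-CD27 2 and 3 as 1 sample or left out of TRB comparisons were chosen after the result was seen. Of 6240 values of 325 results past the threshold, 5013 kept the call and the direction, 1178 lost the call, 44 lost it with the direction turned, and 5, all list medians, kept the call with the direction turned. T cell shares kept both in 28 of 28 values and in 52 of 52 with a mouse left out, other cell type shares in 149 of 154 and 257 of 286, named genes in 1803 of 2243 and 1684 of 2180, and gene lists in 359 of 517 and 681 of 780. Of 3869 values of 223 results not past it, 217 turned direction and stayed there, 68 came to pass and 1 passed with the direction turned. Shares compared between single arms could hardly pass with so few mice, so their staying below the threshold shows no stability. Counts of changed genes stayed within 1.5 times in 109 of 147 and 59 of 99.

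List calls numbered 99 of 263 with the preset correlation, 3 with an estimated correlation and 33 with fry. The cause was not tested for the counts that follow, except that fits of only the arms compared hold fewer mice and those with 3 cells per clone fewer cells. With library weights, combination against AdHER2 gave 400 genes in CD4, 1218 in CD8 and 201 in regulatory T cells, combination against anti-CD27 gave 209 in CD8 and 65 in regulatory T cells, vaccination 75 in regulatory T cells and 2354 in macrophages, anti-CD27 against control 2098, and the macrophage interaction 138. With only the arms compared, the counts were 2 (CD4, against AdHER2), 10 (CD4, against anti-CD27), 8 (CD8), 1 (regulatory) and 294 (macrophages, anti-CD27 against control). Without the filter, they were 87 (CD4) and 54 (CD8) for combination against anti-CD27, and 50, 597 and 0 for macrophages with anti-CD27, the vaccine and their interaction. With 10 cells per library CD8 gave 15, and with 50 cells regulatory T cells gave 1 against anti-CD27, macrophages 29 with anti-CD27 and 1 for the interaction. Quantile normalization gave 214 (CD8), 502 (regulatory, vaccine) and 18 (macrophages, anti-CD27). Pseudocount 1 gave 55 in CD8 cells, and pseudocount 50 gave 3 in macrophages against AdHER2 and 4 for the interaction. Depth as a covariate gave 415 in regulatory T cells with vaccination, and cells of 1500 to 4000 UMIs 0 in macrophages with anti-CD27. With anti-CD27 2 and 3 as 1 sample, macrophages gave 3 with anti-CD27 and 700 with the vaccine. Expanded CD4 cells gave 16 genes at 3 or more cells per clone and 28 among cells typed as CD4 T cells, where combination against anti-CD27 gave 126.

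With 1 mouse left out, counts ran from 26 to 310 (CD4, combination against anti-CD27), 18 to 1087 (CD8), 470 to 2671 (regulatory, vaccine), and in macrophages 0 to 142 (combination against AdHER2), 3 to 11 (anti-CD27), 600 to 2277 (vaccine) and 1 to 55 (interaction), and 13 to 101 for expanded CD4 cells. TRB sharing, which did not pass in the main analysis, ran from 0.601 to 1.10 points and passed only without anti-CD27 2 or 3. It passed at 0.916 with sequences of shared barcodes left out (1.12 and 1.16 without anti-CD27 2 or 3). With nucleotide sequences it was −0.0367 and did not pass, but passed at 0.295 and 0.277 without either. Thinned to the smallest library (−0.0434) and with the Morisita-Horn index (0.410) it did not pass, nor without either mouse. Without thinning the vaccine effect on the expanded share reversed, to 31.2 points, since larger libraries hold more repeats of a clone. Correlations between mice were of values centred on each arm, so mice of 1 arm tend to oppose each other. In CD4 cells AdHER2 1 thus had 0.0369 and −0.0369 with anti-CD27 1 and 3. Mice with equal replicate numbers had mean correlations of 0.142 in CD4, 0.163 in CD8 and 0.0576 in regulatory T cells and −0.0167 in macrophages. The lowest pairs were −0.00976, 0.0175, −0.0796 and −0.427, so not every pair exceeded 0.1 in any class and the numbers were not taken to pair mice. Between AdHER2 and combination, CD4 cells of equal number had 0.481, 0.109 and 0.273. Across numbers, AdHER2 1 correlated with combination 1 and 2 (0.481 and 0.463 in CD4, 0.626 and 0.590 in CD8). It correlated inversely with combination 3 and 4 (−0.311 and −0.461, −0.428 and −0.568). AdHER2 3 showed the reverse in both classes. Inverse values of this kind follow in part from the centring. This grouping was not adjusted for in the main fits, and its cause was not tested. With the replicate numbers as a block the interaction gave 1 gene, CD8 cells 10 for combination against anti-CD27, and VR T cells and MDSC an adjusted p of 0.219. The Th1 median of CD4 T cells for combination against AdHER2 was then 0.25 and the cytotoxic median 0.68, and camera still called each.

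DESeq2 and RLE size factors were not run because the deposited values are corrected scores, and Scrublet calls were too few to use. With the depth and the mice at hand, neither of which was varied, simulated changes of 2-fold were recovered in 12% (CD4), 6% (CD8) and 16% (macrophages) of genes for combination against AdHER2, and 4-fold in 92%, 72% and 81%, with 5, 0 and 19 false calls.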

Other observations

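The tests of repeated cells and shared clones were chosen after the result was seen. Of the 305 repeated T cells of anti-CD27 3, 144 (47.2%, 95% Wilson interval 41.7 to 52.8) carried a receptor found under the same barcode in the receptor library of anti-CD27 1, and 0 in its own, which allows up to 1.24% (Wilson). Of its 645 other T cells, 317 (49.1%) matched its own receptor library, 29 (4.50%, 3.15 to 6.38) that of anti-CD27 1 and 17 (2.64%, 1.65 to 4.18) that of anti-CD27 2. The 93 paired clones common to anti-CD27 2 and anti-CD27 3 held 229 of 381 and 315 of 654 paired cells (60.1 and 48.2%), where the next highest pair of mice shared 21 clones. The receptor libraries of these mice also shared 56 barcodes where chance would give 0.517, with similar UMI totals (Spearman 0.946), and those of anti-CD27 2 and combination 1 shared 21 where chance would give 5.33 (Spearman −0.0242). Whether both libraries come from 1 animal cannot be decided from these files.

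A productive TRB contig was found in 30.8% ± 11.7 of T cells in controls (n = 3), 52.0% ± 6.50 with anti-CD27 (n = 3), 72.4% ± 2.86 with AdHER2 (n = 3) and 81.1% ± 1.02 with the combination (n = 4). Human ERBB2 was above 0 in 7.09% of non-immune cells pooled over all mice, where the next type, immature T cells, stood at 2.17%. As means over vaccinated mice with enough cells, it was above 0 in 0.32% ± 0.56 of non-immune cells (n = 3) and in at most 2.47% of the types measured.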
